A study of Rattus norvegicus with 8 samples.

How the data were processed

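RNA sequencing libraries of 4 groups with 2 replicates each were used: rat embryonic stem cells (ESC), epiblast-like cells (EpiLC), day 3 primordial germ cell-like cells (PGCLC_d3) and such cells after 3 days with gonadal somatic cells (PGCLC_d3ag3). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, both PGCLC groups were sorted for a tdTomato reporter of Nanos3, although the labels list the genotype as wild type. Per the labels' protocols, RNA was taken up with a PicoPure kit and libraries were made with SMART-Seq v4 Ultra Low Input and KAPA Hyper Prep kits.

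Per the submitters' processing notes, reads were extracted with bcl2fastq 2.20, trimmed with cutadapt 1.1.6, mapped to the rat genome build rn7 with HISAT2 2.1.0 and counted with featureCounts of Subread 1.6.5. The deposited values are log2(TPM+1), made by the authors from TPM per gene and sample. The feeder cells of the ESC were mouse cells per the labels' protocols, and how their reads map to the rat genome was not tested. The table holds 22228 named genes and 11066 blank rows, which were left out. The gene reference at hand is of another rat genome build, so no coordinates are given.

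Depth was estimated from the steps between the lowest TPM values of a gene, which correspond to single reads. Relative to ESC replicate 1, at 1, the depth was 1.37 for ESC replicate 2, 1.16 and 1.5 for EpiLC, 1.32 and 1.14 for PGCLC_d3, and 2.17 and 2.38 for PGCLC_d3ag3. Of the low values 91.1% to 93.3% were whole numbers of reads within 0.06, and on simulated data the largest error was 0.55%. The estimate is relative, so read totals are not given. For genes with few reads, a chi-square test set the difference between replicates against counting noise. The mean chi-square per gene was 1.38 in ESC (199 genes, chi-square p = 3.2e-04), 1.51 in EpiLC (368 genes, chi-square p = 9.2e-10), 1.42 in PGCLC_d3 (374 genes, chi-square p = 1.2e-07) and 4.54 in PGCLC_d3ag3 (601 genes, chi-square p = 2.2e-267). Simulated replicates that differ by counting noise alone gave 0.898 to 1.07. Reads of amplified libraries are not independent molecules, so an excess says little about how the replicates were made.

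Genes with TPM of at least 1 in at least 2 of the 8 samples, 13571 in all, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, 2-sided, on the deposited log2 values). All 4 groups were fitted together, with 4 residual degrees of freedom, a median prior of 5.46 and a median residual SD of 0.117. A gene is called changed at a Benjamini-Hochberg adjusted p under 0.05 over the tested genes of a comparison. The comparisons are EpiLC versus ESC, PGCLC_d3 versus EpiLC, PGCLC_d3ag3 versus PGCLC_d3 and PGCLC_d3 versus ESC. Changes of 0.5, 1 and 2 on the log2 scale were planted in 67, 67 and 66 of 13571 simulated genes with normal noise. The fit found 55.2%, 100% and 100% of them for EpiLC versus ESC with 9 false calls, 52.2%, 94% and 100% for PGCLC_d3 versus EpiLC with 13, 56.7%, 97% and 100% for PGCLC_d3ag3 versus PGCLC_d3 with 10, and 62.7%, 97% and 100% for PGCLC_d3 versus ESC with 18. Far more genes were called in the data than were changed in these simulations. The shares found and the numbers of false calls therefore do not carry over to the calls of this report.

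Before the data were examined, 31 gene lists were fixed from general knowledge: naive pluripotency, general pluripotency, formative and primed epiblast, primitive streak and mesoderm, neural ectoderm, endoderm, early germ cell specification, gonadal germ cell, meiosis, DNA methylation, DNA demethylation, histone methylation, BMP targets, FGF and ERK targets, WNT targets, LIF and STAT3 targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, G2 and M cell division, p53 targets, immediate early and dissociation stress, imprinted, HOX, gonadal somatic cell, fibroblast and feeder, endothelial and blood, trophoblast and amnion, cytosolic ribosomal proteins, epithelial and mesenchymal, and X and Y linked genes. Lists with at least 5 tested members were tested with camera of limma, with a preset correlation of 0.01 between genes and adjustment over the lists of a comparison. This test sets the genes of a list against all other genes. With a correlation estimated per list, camera also has only the 4 residual degrees of freedom, so few lists can pass. The X and Y linked list has 4 tested members and was not tested as a list. The list members Tcl1, Dppa2, Fgf15, Rhox6, Tex19, Suv39h1, Hspa1a, H19, Meg3, Hoxa10, Rps19 and Xist were not analysed here.

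Genes named in the report follow a rule fixed at the same time. They are genes listed in advance for each comparison, the 5 largest rises and 5 largest falls past the test with separate groups and a mean of at least 10 TPM in the higher group, leaving out clone-style symbols, and the 3 members with the largest change in the list's direction of each list that passed. Some genes that the rule names are not reported here. The Y-linked genes of the X and Y linked list were also set in advance to be given as levels per group. Other genes outside this rule are said to be chosen after their values were seen. Members of families with near-identical copies may share reads, which concerns ribosomal protein, haemoglobin, RT1, tubulin and Pramel genes and Y-linked genes with X copies.

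The alternatives tried were a pseudocount of 0.1, no filter on low values (19132 genes), TPM of at least 5 in 2 samples (10809 genes), median-of-ratios rescaling, quantile normalization, the 2 groups fitted alone, eBayes without trend, robust eBayes, the replicate number as a block, an absolute log2 change of at least 1, leaving out each replicate in turn, and for lists a correlation estimated per list. Overlaps of calls were set beside independent lists and beside 100 simulations of unchanged groups in which both comparisons used the same simulated EpiLC libraries. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.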

Results

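RNA sequencing measured gene expression at 4 steps from rat embryonic stem cells to primordial germ cell-like cells, the in vitro counterparts of the founder cells of sperm and eggs. Embryonic stem cells (ESC) of the strain Crlj:WI grew on mouse fibroblast feeders with MEK and GSK3 inhibitors (PD0325901 at 1 µM and CHIR99021 at 3 µM) and rat LIF. Epiblast-like cells (EpiLC) were aggregates kept for 60 h with activin A at 20 ng/ml and bFGF at 12 ng/ml. Cells sorted for a tdTomato reporter of Nanos3 after 3 days with BMP4 at 500 ng/ml, SCF, EGF and LIF form the group PGCLC_d3. The group PGCLC_d3ag3 holds reporter-positive cells sorted 3 days after 5000 PGCLC_d3 cells were mixed with 50000 somatic cells of E15.5 female gonads, from which c-KIT-positive germ cells had been depleted. Each group has 2 libraries, 8 in all. No label says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Values are log2(TPM+1) as deposited, given here as TPM with mean ± SD (n = 2 libraries) and as differences of log2(TPM+1), which understate the change of genes with low values.

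Replicates lay close together, with Pearson correlations across tested genes of 0.997 for ESC, 0.9968 for EpiLC, 0.9975 for PGCLC_d3 and 0.9946 for PGCLC_d3ag3. These correlations run across genes, which are not independent replicates. The first principal component held 51.1% of the variance and set ESC and EpiLC apart from both PGCLC groups. The second held 28.9% and set EpiLC apart from ESC and PGCLC_d3ag3. TPM keeps no read totals. Steps between the lowest values put the depth of each library, relative to ESC replicate 1, at 1.37 for ESC replicate 2, 1.16 and 1.5 for EpiLC, 1.32 and 1.14 for PGCLC_d3, and 2.17 and 2.38 for PGCLC_d3ag3.

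**Figure D1:**
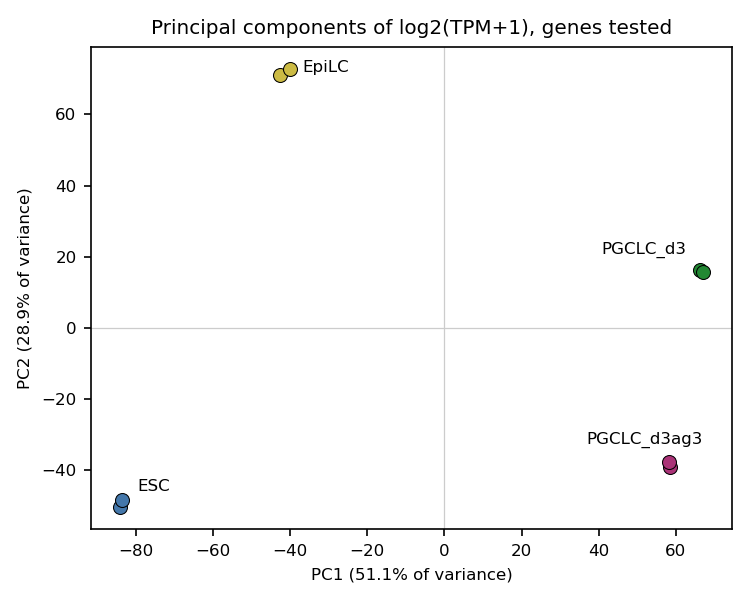
Principal components of log2(TPM+1) over the 13571 tested genes, with each of the 8 libraries as a point coloured by group, PC1 (51.1% of variance) on the x axis and PC2 (28.9%) on the y axis. Replicates of a group lie next to each other, with ESC at PC1 -84.0 and -83.6, EpiLC at -42.6 and -39.9, and both PGCLC groups above 58.

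The step from ESC to EpiLC asks how naive pluripotent cells change when they are brought to a state resembling the post-implantation epiblast. Nanog, a core pluripotency transcription factor, went from TPM 922 ± 14.9 in ESC to 4.89 ± 0.926 (SD, n = 2) in EpiLC, a log2 change of -7.30 (SE 0.105). Tbx3 fell from 343 ± 9.61 to 0.422 ± 0.111, Esrrb from 118 ± 10.3 to 0.748 ± 0.312 and Klf4 from 47.2 ± 0.496 to 1.29 ± 0.228, all 3 transcription factors that support the naive state. The transcription factor genes Otx2 and Pou3f1 rose, Otx2 from 0.398 ± 0.049 to 74.2 ± 0.479 and Pou3f1 from 1.07 ± 0.019 to 214 ± 5.70. The de novo DNA methyltransferases Dnmt3a and Dnmt3b rose to 200.4 ± 6.02 and 2777 ± 156, from 14.9 ± 2.00 and 149 ± 8.32 in ESC.

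Other genes listed in advance moved as well. Zfp42 changed by log2 -2.90 and Tfcp2l1 by -2.53, and Prdm14, which represses DNA methyltransferase genes, fell from 16.9 ± 0.867 to 0.061 ± 0.087. Sox2 fell from 217 ± 8.55 to 23.9 ± 3.70, and Pou5f1, which encodes OCT4, from 517 ± 1.27 to 277 ± 17.5. The epiblast growth factor gene Fgf5 was listed at 0 in both ESC libraries and at 0.037 ± 0.053 in EpiLC, too low to be tested, and Wnt3 was at 0.035 ± 0.049 and 0.090 ± 0.057 (adjusted p = 0.628). The mesoderm factor Tbxt fell from 3.34 ± 0.359 to 0.105 ± 0.083 and the cadherin Cdh2 from 4.06 ± 0.273 to 0.887 ± 0.066. Among the largest rises with an EpiLC mean of at least 10 TPM were the tubulin gene Tubb4a (0.170 ± 0.003 to 294 ± 30.5), Pclaf, which encodes a PCNA-binding protein (0.886 ± 0.235 to 279 ± 0.686), Mcf2 (0.208 ± 0.185 to 105 ± 4.97) and the villin gene Vil1 (0.218 ± 0.104 to 99.5 ± 1.63). Among the largest falls were Pramel6 (643 ± 33.4 to 0.402 ± 0.140), the maternal-effect gene Ooep (959 ± 16.0 to 1.39 ± 0.805) and Zfp93 (315 ± 3.41 to 0.638 ± 0.069). Pramel6 belongs to a multigene family whose copies may share reads, so its level is uncertain.

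Of 14 tested naive pluripotency genes 13 fell, 0 rose and 1 did not pass (adjusted p = 1.1e-07 and adjusted p = 0.25 with an estimated correlation). All 8 tested HOX genes, which pattern the body axis, fell (adjusted p = 8.3e-05 and adjusted p = 0.25 with an estimated correlation). Hoxa7 was at 97.3 ± 6.98 in ESC and 0.748 ± 0.063 in EpiLC, and Hoxa9 at 37.2 ± 0.824 and 0.051 ± 0.042. LIF and STAT3 targets fell (9 of 12, with 2 up; adjusted p = 0.00129 and adjusted p = 0.286 with an estimated correlation). Among them were Socs3 (186 ± 8.16 to 3.36 ± 0.516) and Bcl3 (log2 -6.43). In the early germ cell list 9 of 15 fell and 4 rose (adjusted p = 0.00638 and adjusted p = 0.25 with an estimated correlation). Dppa3 went from 1309 ± 4.50 to 32.7 ± 8.44, Klf2 from 1966 ± 12.5 to 90.4 ± 8.18 and the alkaline phosphatase gene Alpl from 292 ± 27.0 to 9.85 ± 0.346. Primitive streak and mesoderm genes fell in 9 of 14 and rose in 3 (adjusted p = 0.0164 and adjusted p = 0.478 with an estimated correlation). Among them were the caudal homeobox genes Cdx2 (125 ± 13.5 to 0.143 ± 0.130) and Cdx1 (35.6 ± 1.92 to 0.030 ± 0.042) and Msx2 (26.4 ± 1.29 to 0.498 ± 0.040).

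Gonadal germ cell genes rose: 17 of 23 were higher in EpiLC and 2 lower (adjusted p = 0.00913 and adjusted p = 0.65 with an estimated correlation). Dazl was at 2.48 ± 0.376 and 13.6 ± 0.043, Tex14 at 0.976 ± 0.102 and 9.33 ± 1.49 and Taf7l at 0.335 ± 0.107 and 6.30 ± 1.12. Imprinted genes rose in 15 of 19 and fell in 2 (adjusted p = 0.0187 and adjusted p = 0.348 with an estimated correlation). Among them were Mest (182 ± 14.5 to 2040.1 ± 36.0), Peg10 (4.93 ± 1.63 to 75.9 ± 4.71) and Magel2 (0.023 ± 0.005 to 3.53 ± 0.282). Oxidative phosphorylation genes fell by small amounts, 23 of 31 with a list median of -0.25 and 3 up (adjusted p = 0.00331 and adjusted p = 0.348 with an estimated correlation); Atp5po changed by log2 -0.70, Ndufa4 by -0.62 and Uqcrc1 by -0.59. Cholesterol synthesis genes fell in 14 of 23 and rose in 4 (adjusted p = 0.0203 and adjusted p = 0.65 with an estimated correlation). Log2 changes were -1.51 for Ebp, -1.35 for Dhcr7 and -1.30 for Mvk. That list call ended with adjusted p = 0.0585 without ESC replicate 1 and with adjusted p = 0.051 under quantile normalization, and the streak call ended with adjusted p = 0.0621 over genes with TPM of at least 5.

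The other lists did not pass the list test in EpiLC. General pluripotency had 7 rises and 4 falls among 11 genes (adjusted p = 0.453), and in the formative and primed epiblast list 8 of 18 rose and 8 fell (adjusted p = 0.712). In neural ectoderm 3 of 5 rose and 1 fell (adjusted p = 0.478). In endoderm 2 of 8 rose and 3 fell (adjusted p = 0.758). In meiosis 7 of 18 rose and 2 fell (adjusted p = 0.712). In DNA methylation 4 of 9 rose and 3 fell (adjusted p = 0.712). In DNA demethylation 3 of 8 rose and 4 fell (adjusted p = 0.797). In histone methylation 10 of 14 rose and 2 fell (adjusted p = 0.0617). Of BMP targets 3 of 15 rose and 5 fell (adjusted p = 0.322), with a list median of 0.05 that was -0.23 under quantile normalization. Of FGF and ERK targets 10 of 17 rose and 6 fell (adjusted p = 0.478). Of WNT targets 4 of 16 rose and 9 fell (adjusted p = 0.0617). Of glycolysis genes 5 of 18 rose and 9 fell (adjusted p = 0.478). Of G2 and M cell division genes 5 of 21 rose and 9 fell (adjusted p = 0.4). Of p53 targets 10 of 15 rose and 1 fell (adjusted p = 0.127). Of immediate early and dissociation stress genes 7 of 15 rose and 4 fell (adjusted p = 0.672). Of gonadal somatic cell genes 8 of 15 rose and 3 fell (adjusted p = 0.478). Of endothelial and blood genes 1 of 7 rose and 2 fell (adjusted p = 0.478). Of trophoblast and amnion genes 4 of 11 rose and 4 fell (adjusted p = 0.712), against 4 and 5 under quantile normalization. Of cytosolic ribosomal protein genes 4 of 24 rose and 2 fell (adjusted p = 0.797). Of epithelial and mesenchymal genes 7 of 11 rose and 2 fell (adjusted p = 0.0617). Of fibroblast and feeder genes 8 of 14 rose and 4 fell (adjusted p = 0.362), with the matrix gene Dcn at 0.274 ± 0.018 in ESC and 12.7 ± 4.31 in EpiLC, Col3a1 at 9.66 ± 1.04 and 22.1 ± 13.5, and Col1a1 at 10.5 ± 2.36 and 10.4 ± 5.68. Dcn, Col3a1 and Col1a1 were chosen here after their values were seen. WNT targets passed, down, over genes with TPM of at least 5 (adjusted p = 0.0235). Histone methylation genes, up, and WNT targets, down, passed the list test under quantile normalization (adjusted p = 0.0363 for each) and without a filter on low values (adjusted p = 0.0333 for each). Epithelial and mesenchymal genes passed, up, without the filter (adjusted p = 0.0333) and without EpiLC replicate 1 (adjusted p = 0.0479), and p53 targets passed, up, without ESC replicate 2 (adjusted p = 0.0306). Adjusted over the list alone, the counts of rises and falls were as over all genes except for glycolysis (5 and 10), oxidative phosphorylation (4 and 23), cholesterol synthesis (4 and 15), endoderm (2 and 2), histone methylation (11 and 2), fibroblast (9 and 4), ribosomal proteins (4 and 1) and epithelial and mesenchymal genes (8 and 2). The list median, mean and test differed in sign for the formative list (-0.01, 1.18, up), BMP targets (0.05, -1.44, down), glycolysis (-0.21, 0.22, down) and trophoblast and amnion (0.07, -0.67, down), and for endothelial and blood genes the median was 0 and the mean -0.74.

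In limma with Benjamini-Hochberg adjustment 9129 of 13571 tested genes changed between EpiLC and ESC, 4807 higher in EpiLC and 4322 lower. With a log2 change of at least 1 added, 1698 were higher and 1467 lower. The median gene changed by 0.04, by 0.04 after median-of-ratios rescaling and by 0.002 after quantile normalization, and the share of changed genes that were higher was 52.7%, 53.2% and 51.0% in turn. The list test was camera with a preset correlation of 0.01, and none of its 9 calls in this comparison passed with an estimated correlation. The latter setting also leaves the test only 4 residual degrees of freedom. The lost calls therefore do not show that correlation between genes undoes them.

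**Figure D2:**
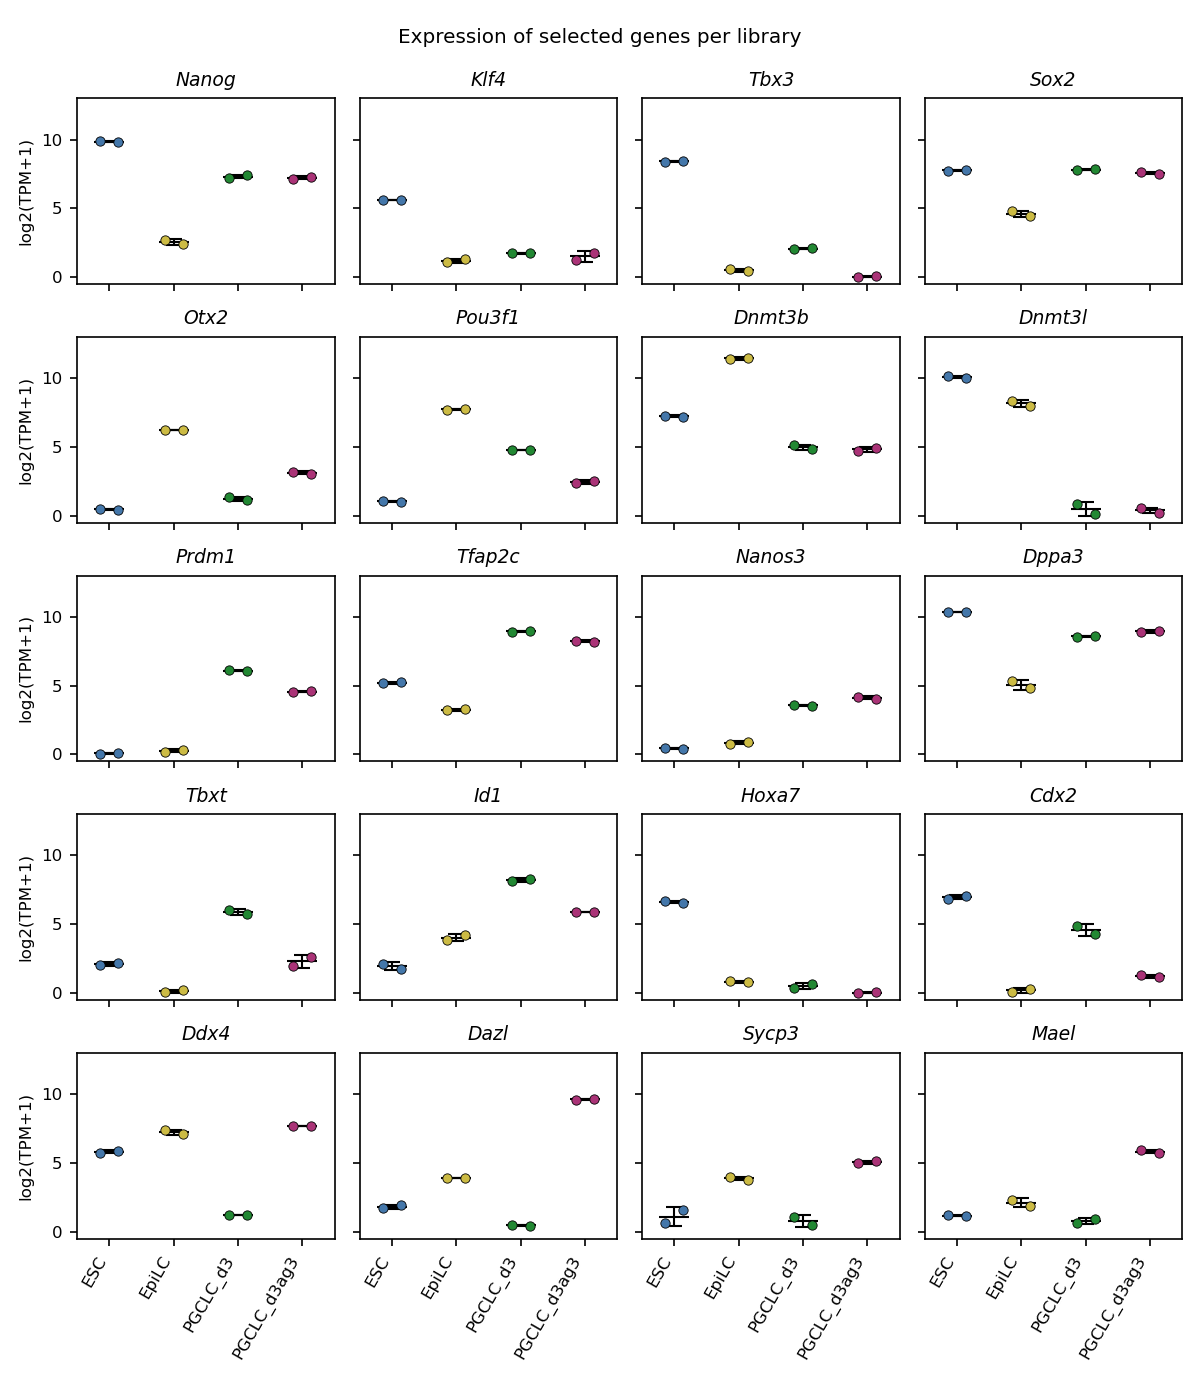
Expression of 20 genes in log2(TPM+1) on the y axis against the 4 groups on the x axis, with each library as a point, the group mean as a bar and the SD of 2 libraries as whiskers. Nanog is low in EpiLC, Prdm1 and Tfap2c are highest in PGCLC_d3, and Dazl, Sycp3 and Mael are highest in PGCLC_d3ag3.

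From EpiLC to PGCLC_d3 the question is which genes change as cells take on the germ cell fate under BMP4, SCF, EGF and LIF. PGCLC_d3 cells were sorted for the reporter, so changes within cells cannot be told apart from the selection of some cells. Prdm1, which encodes the repressor BLIMP1, went from TPM 0.204 ± 0.087 in EpiLC to 66.5 ± 1.55 (SD, n = 2) in PGCLC_d3, a log2 change of 5.81 (SE 0.119). Prdm14 rose from 0.061 ± 0.087 to 86.0 ± 3.75 and Tfap2c, the third factor of the germ cell specification network, from 8.47 ± 0.348 to 492 ± 7.50. Dnd1, an RNA-binding protein gene of germ cells, rose from 9.72 ± 1.90 to 373 ± 2.02, the SCF receptor gene Kit from 13.9 ± 1.55 to 398 ± 1.18, and Dppa3 from 32.7 ± 8.44 to 382 ± 9.58. Nanos3, whose reporter was used for the sort, was at 0.804 ± 0.144 and 10.8 ± 0.220.

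Nanog rose from 4.89 ± 0.926 to 159 ± 15.2 and Sox2 from 23.9 ± 3.70 to 222 ± 7.33, whereas Pou5f1 fell from 277 ± 17.5 to 186 ± 6.68. Klf4 went from 1.29 ± 0.228 to 2.32 ± 0.024 (log2 0.54, adjusted p = 0.0174), a call that ended with adjusted p = 0.0683 under median-of-ratios rescaling, 0.156 under quantile normalization and 0.0623 to 0.112 without EpiLC replicate 1 or either PGCLC_d3 replicate. The formative factor Otx2 fell from 74.2 ± 0.479 to 1.36 ± 0.259. Fgf5 was listed at 0 in both PGCLC_d3 libraries. Among the largest rises were Psmb8, an immunoproteasome subunit gene (0.536 ± 0.490 to 521 ± 12.5), the tetraspanin gene Tspan8 (1.20 ± 0.930 to 390.4 ± 14.2) and the heat shock gene Hspb1 (1.71 ± 1.02 to 310.4 ± 19.8). Among the largest falls were Sohlh2, a germ cell transcription factor gene (94.5 ± 13.4 to 0.251 ± 0.026), Fgf4 (78.1 ± 10.4 to 0.180 ± 0.086) and Dnmt3l.

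The early germ cell list rose, 12 of 15 genes with 3 down (adjusted p = 0.0056 and adjusted p = 0.309 with an estimated correlation). DNA methylation genes fell, 7 of 9 with 0 up (adjusted p = 7.4e-05 and adjusted p = 0.315 with an estimated correlation). Dnmt3b fell from 2777 ± 156 to 30.7 ± 4.40, Dnmt3a from 200.4 ± 6.02 to 2.71 ± 0.009, Dnmt3l from 293 ± 53.6 to 0.490 ± 0.518 and the maintenance factor Uhrf1 from 32.7 ± 1.09 to 7.55 ± 0.402. BMP targets rose, 14 of 15 with 1 down (adjusted p = 4.7e-05 and adjusted p = 0.315 with an estimated correlation). Among them were Id1 (15.4 ± 2.72 to 298 ± 27.9), Id3 (14.2 ± 2.13 to 873 ± 46.2), Msx1 (0.523 ± 0.160 to 175 ± 2.84) and Msx2 (0.498 ± 0.040 to 142 ± 13.4). WNT targets rose in 13 of 16 and fell in 3 (adjusted p = 0.0257 and adjusted p = 0.386 with an estimated correlation). Among them were the feedback inhibitors Notum (0.205 ± 0.148 to 51.3 ± 5.22) and Nkd1 (0.981 ± 0.249 to 61.6 ± 4.93).

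Primitive streak and mesoderm genes rose in 11 of 14 and fell in 1 (adjusted p = 0.00735 and adjusted p = 0.315 with an estimated correlation). Tbxt went from 0.105 ± 0.083 to 58.0 ± 8.53. Trophoblast and amnion genes rose in 10 of 11 and fell in 1 (adjusted p = 0.0057 and adjusted p = 0.309 with an estimated correlation). Hand1 was at 3.19 ± 0.508 and 53.5 ± 0.187, Dlx3 at 0.456 ± 0.039 and 25.8 ± 0.210 and the keratin gene Krt19 at 1.05 ± 0.418 and 23.1 ± 2.84. Hand1, Msx1, Msx2 and Tbxt are among the members of more than 1 of these lists, so the list calls are not separate support. Fibroblast and feeder genes fell in 9 of 14 and rose in 2 (adjusted p = 0.0057 and adjusted p = 0.386 with an estimated correlation). Col3a1 was at 22.1 ± 13.5 and 0.505 ± 0.688, Col1a1 at 10.4 ± 5.68 and 1.14 ± 0.933, and Dcn, at 12.7 ± 4.31 in EpiLC, was listed at 0 in both PGCLC_d3 libraries.

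Glycolysis genes fell, 17 of 18 with 0 up and a list median of -1.64 (adjusted p = 7.1e-10 and adjusted p = 0.309 with an estimated correlation). Gapdh went from 1222 ± 89.2 to 288 ± 37.2, the hexokinase gene Hk2 from 61.9 ± 0.648 to 12.1 ± 1.77 and the phosphofructokinase gene Pfkm from 204 ± 33.5 to 21.4 ± 0.274. Cholesterol synthesis genes fell in 16 of 23 and rose in 3 (adjusted p = 1.9e-04 and adjusted p = 0.315 with an estimated correlation). Acat2 changed by log2 -2.41. Gonadal germ cell genes fell in 17 of 23 and rose in 3 (adjusted p = 5.8e-06 and adjusted p = 0.315 with an estimated correlation). Ddx4, an RNA helicase gene of germ cells, fell from 148 ± 20.2 to 1.29 ± 0.018, Dazl from 13.6 ± 0.043 to 0.369 ± 0.030, Fkbp6 from 24.2 ± 3.28 to 0.108 ± 0.032 and Stk31 from 15.7 ± 2.09 to 0.501 ± 0.210. General pluripotency genes fell in 8 of 11 and rose in 2 (adjusted p = 0.0057 and adjusted p = 0.309 with an estimated correlation). Tdgf1 was at 627 ± 36.9 and 35.8 ± 2.94, Dppa4 at 175 ± 0.948 and 30.8 ± 1.67 and L1td1 at 608 ± 34.0 and 184 ± 9.32. The p53 targets fell in 8 of 15 and rose in 2 (adjusted p = 0.0128 and adjusted p = 0.41 with an estimated correlation). Among them were Cdkn1a at log2 -1.88, Eda2r at -1.56 and Phlda3 at -1.40. Formative and primed epiblast genes fell in 10 of 18 and rose in 7 (adjusted p = 0.0257 and adjusted p = 0.309 with an estimated correlation). Sox3 was at 77.0 ± 3.56 and 0.995 ± 0.199. Dnmt3a and Dnmt3b belong to this list as well as to the DNA methylation genes. The formative list call ended under median-of-ratios rescaling (adjusted p = 0.118) and quantile normalization (adjusted p = 0.0935).

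The other lists did not pass the list test in PGCLC_d3. Of naive pluripotency genes 9 of 14 rose and 5 fell (adjusted p = 0.486). Of neural ectoderm genes 3 of 5 rose and 2 fell (adjusted p = 0.674). Of endoderm genes 7 of 8 rose and 0 fell (adjusted p = 0.0529). Of meiosis genes 6 of 18 rose and 9 fell (adjusted p = 0.0984). Of histone methylation genes 3 of 14 rose and 7 fell (adjusted p = 0.0767). Of FGF and ERK targets 11 of 17 rose and 2 fell (adjusted p = 0.187). Of LIF and STAT3 targets 9 of 12 rose and 2 fell (adjusted p = 0.0895). Of DNA demethylation genes 4 of 8 rose and 3 fell (adjusted p = 0.835), a balance that turned to 3 and 4 under both rescalings. Of oxidative phosphorylation genes 19 of 31 rose and 7 fell (adjusted p = 0.486), against 10 and 12 after median-of-ratios rescaling. Of G2 and M genes 10 of 21 rose and 5 fell (adjusted p = 0.756), against 8 and 9 after that rescaling. Of ribosomal protein genes 13 of 24 rose and 1 fell (adjusted p = 0.232), against 5 and 5, and quantile normalization put this list past the test (adjusted p = 0.00144) as it did oxidative phosphorylation (adjusted p = 0.0198), both up. Of immediate early genes 7 of 15 rose and 2 fell (adjusted p = 0.486). Of imprinted genes 9 of 19 rose and 6 fell (adjusted p = 0.848), with a list median of 0.23 that was -0.04 under quantile normalization. Of HOX genes 3 of 8 rose and 0 fell (adjusted p = 0.956). Of endothelial and blood genes 3 of 7 rose and 3 fell (adjusted p = 0.476). Of gonadal somatic cell genes 7 of 15 rose and 6 fell (adjusted p = 0.563), against 6 and 6 after either rescaling. Of epithelial and mesenchymal genes 4 of 11 rose and 5 fell (adjusted p = 0.247). Endoderm genes passed, up, without a filter on low values (adjusted p = 0.0452), without the trend (adjusted p = 0.0366), without EpiLC replicate 2 (adjusted p = 0.0381) and without PGCLC_d3 replicate 2 (adjusted p = 0.0318). Endoderm genes and LIF and STAT3 targets passed, both up, under median-of-ratios rescaling (adjusted p = 0.0239 and adjusted p = 0.0275) and under quantile normalization (adjusted p = 0.0373 for each), and histone methylation genes passed, down, under the former (adjusted p = 0.0247). Adjusted over the list alone, the counts were as over all genes except for imprinted genes (9 and 7) and fibroblast genes (3 and 9). The sign of the list test was down where median and mean were up for DNA demethylation (0.14 and 0.15) and gonadal somatic cell genes (0.15 and 0.24), and endothelial and blood genes had a median of 0 and a mean of -0.16.

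In limma 10171 of 13571 genes changed between PGCLC_d3 and EpiLC, 6424 higher and 3747 lower, or 2542 and 1470 with a log2 change of at least 1. The median gene rose by 0.21 on the log2 scale, which median-of-ratios rescaling brought to 0.003 and quantile normalization to 0.013. The share of changed genes that were higher was 63.2% as deposited, 50.3% after median-of-ratios rescaling and 50.8% after quantile normalization, so small changes have no firm direction. None of the 13 list calls passed with an estimated correlation.

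Cells kept for 3 days with gonadal somatic cells were compared with PGCLC_d3 to ask how they differ after this step. No group was cultured for 3 more days without gonadal cells. Contact with gonadal cells, time in culture and any change of medium therefore cannot be told apart. Dazl, an RNA-binding protein gene needed for germ cell development, went from TPM 0.369 ± 0.030 in PGCLC_d3 to 785 ± 30.4 (SD, n = 2) in PGCLC_d3ag3, a log2 change of 9.16 (SE 0.105). Ddx4 rose from 1.29 ± 0.018 to 202 ± 2.29, and Mael and Piwil2, of the piRNA pathway, from 0.701 ± 0.248 to 55.5 ± 4.87 and from 2.86 ± 0.096 to 61.5 ± 2.91. The synaptonemal complex gene Sycp3 rose from 0.755 ± 0.537 to 31.9 ± 2.03, while Stra8, a gene of meiotic entry, was at 0.477 ± 0.214, too low to be tested. Of the genes listed in advance, Prdm1 fell from 66.5 ± 1.55 to 22.8 ± 0.886, Prdm14 from 86.0 ± 3.75 to 37.6 ± 3.00 and Tfap2c from 492 ± 7.50 to 301 ± 9.02.

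Kit fell from 398 ± 1.18 to 277 ± 13.7 and Pou5f1 from 186 ± 6.68 to 130.0 ± 3.85, while Nanos3, the reporter gene of the sort, rose from 10.8 ± 0.220 to 16.4 ± 1.12. Nanog was at 159 ± 15.2 and 149 ± 10.2, a log2 difference of -0.09 (adjusted p = 0.49) that was 0.09 after median-of-ratios rescaling. Dppa3 changed by 0.35 (adjusted p = 0.0345) and Sox2 by -0.24 (adjusted p = 0.0407), calls that ended without any 1 of the 4 libraries compared, without a filter on low values and without the trend. The Sox2 change was -0.07 (adjusted p = 0.538) after median-of-ratios rescaling, and the Dppa3 call also ended under quantile normalization (adjusted p = 0.114) and robust eBayes (adjusted p = 0.0507). Dnmt1 changed by -0.38 (adjusted p = 0.00587), which ended under median-of-ratios rescaling (adjusted p = 0.0538) and quantile normalization (adjusted p = 0.109). Uhrf1 was at 7.55 ± 0.402 and 8.15 ± 2.30 (adjusted p = 0.672) and passed under quantile normalization at log2 0.44 and without PGCLC_d3ag3 replicate 1 at 0.33, against -0.18 without replicate 2. Dnmt3b was at 30.7 ± 4.40 and 27.5 ± 3.50 (adjusted p = 0.233), with a sign that turned under both rescalings and a call at -0.29 without PGCLC_d3 replicate 2. Besides Dazl and Ddx4 the largest rises were in Stk31 (0.501 ± 0.210 to 141 ± 5.23), Fcrla (1.96 ± 1.33 to 244 ± 0.962) and the tubulin gene Tuba3b (0.131 ± 0.013 to 97.9 ± 3.44), of which Tuba3b may share reads with close copies. The largest falls were in the NODAL inhibitor gene Lefty2 (102 ± 21.2 to 0.157 ± 0.054), the neurofilament gene Nefm (94.5 ± 22.0 to 0.214 ± 0.302), the cyclin gene Ccnd2 (333 ± 19.3 to 3.29 ± 0.842), Hand1 and the protease gene Tmprss2 (52.4 ± 10.5 to 0.242 ± 0.025).

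Of 23 gonadal germ cell genes 21 rose, 1 fell and 1 did not pass, with a list median of 3.87 (adjusted p = 3.1e-14 and adjusted p = 0.2 with an estimated correlation). Meiosis genes rose in 15 of 18 and fell in 1 (adjusted p = 4.7e-08 and adjusted p = 0.098 with an estimated correlation). Among them were Brdt (2.62 ± 0.108 to 74.6 ± 2.59), the meiotic cohesin gene Smc1b (0.946 ± 0.022 to 39.5 ± 4.20) and Hormad1, listed at 0 in PGCLC_d3 and at 18.6 ± 0.201 in PGCLC_d3ag3. Cholesterol synthesis genes rose in 21 of 23, with 0 falls and a list median of 1.01 (adjusted p = 1.4e-10 and adjusted p = 0.2 with an estimated correlation). Among them were Sqle (56.4 ± 4.04 to 192 ± 10.7), Insig1 (log2 2.00) and Hsd17b7 (6.45 ± 0.026 to 29.4 ± 0.595). Oxidative phosphorylation genes rose in 24 of 31 and fell in 1, with a list median of 0.32 (adjusted p = 4.1e-08 and adjusted p = 0.2 with an estimated correlation). Ndufa1 changed by 0.87, Ndufb8 by 0.81 and Ndufc1 by 0.81. Glycolysis genes rose in 12 of 18 and fell in 4 (adjusted p = 0.00499 and adjusted p = 0.505 with an estimated correlation). Among them were Pdk1 at 2.18, Tpi1 at 1.39 and Hk2 at 1.22. The glycolysis call ended under quantile normalization (adjusted p = 0.127).

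BMP targets fell in 13 of 15 and rose in 0 (adjusted p = 2.7e-04 and adjusted p = 0.307 with an estimated correlation). Id2 was at 533 ± 42.4 and 63.5 ± 5.05, Bambi at 232 ± 20.8 and 27.8 ± 0.735 and Gata2 at 8.29 ± 0.710 and 0.363 ± 0.087. WNT targets fell in 13 of 16 and rose in 1 (adjusted p = 0.00499 and adjusted p = 0.383 with an estimated correlation), with Notum falling from 51.3 ± 5.22 to 3.24 ± 1.00 and Tbxt from 58.0 ± 8.53 to 4.07 ± 1.61. FGF and ERK targets fell in 12 of 17 and rose in 2 (adjusted p = 0.0325 and adjusted p = 0.307 with an estimated correlation). Among them were Phlda1 (263 ± 5.31 to 18.3 ± 0.170), Ccnd1 (15.2 ± 0.405 to 1.21 ± 0.068) and Dusp4 (55.5 ± 1.63 to 8.35 ± 1.07). That call ended with the 2 groups fitted alone (adjusted p = 0.084) and without the trend (adjusted p = 0.0532). Primitive streak and mesoderm genes fell in 12 of 14 and rose in 2 (adjusted p = 0.0049 and adjusted p = 0.307 with an estimated correlation). Hand1 was at 53.5 ± 0.187 and 0.284 ± 0.329, Wnt5a at 42.0 ± 4.34 and 0.790 ± 0.204 and Cdx2 at 23.3 ± 6.76 and 1.34 ± 0.195. Tbxt and Cdx2 belong to this list as well as to the WNT targets. Trophoblast and amnion genes fell in 9 of 11 and rose in 1 (adjusted p = 0.0049 and adjusted p = 0.2 with an estimated correlation). Among them were Krt8 (185 ± 9.93 to 19.6 ± 0.242) and Dlx3 (25.8 ± 0.210 to 1.94 ± 0.001). Imprinted genes fell in 16 of 19 and rose in 0 (adjusted p = 1.0e-03 and adjusted p = 0.2 with an estimated correlation). Mest changed by log2 -2.79, and Peg3 was at 428 ± 22.3 and 62.2 ± 3.77 and Phlda2 at 11.4 ± 2.16 and 0.148 ± 0.051. The p53 targets fell in 14 of 15 and rose in 0 (adjusted p = 0.00371 and adjusted p = 0.426 with an estimated correlation). Phlda3 changed by log2 -1.92, Tnfrsf10b by -1.86 and Gdf15 by -1.22.

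Markers of cells that the aggregates could hold were measured in the same libraries. The gonadal somatic genes Wt1 and Foxl2 were at 1.22 ± 0.078 and 0.375 ± 0.122 in PGCLC_d3ag3, with Wt1 past the test (adjusted p = 1.3e-05) and Foxl2 too low to be tested, and of the list 4 of 15 rose and 4 fell (adjusted p = 0.566), against 6 and 3 under quantile normalization. Of endothelial and blood genes 3 of 7 rose and 2 fell (adjusted p = 0.176), with haemoglobin Hba-a1 at 1.44 ± 0.966 and 39.8 ± 6.06 and Hbb listed at 0 in every PGCLC_d3, EpiLC and ESC library and at 4.81 and 11.3 TPM in the 2 PGCLC_d3ag3 libraries. Hba-a1 has near-identical copies, so its level is uncertain, and it and Hbb were chosen after their values were seen. Of fibroblast and feeder genes 4 of 14 rose and 6 fell (adjusted p = 0.882). The donor gonads were female. Of 4 Y-linked genes in the list, 1 rose and 2 fell, too few for the list test: Ddx3y was at 4.93 ± 1.09 and 18.5 ± 2.17, Kdm5d at 27.9 ± 1.36 and 8.87 ± 1.74, Uty at 11.6 ± 0.340 and 3.77 ± 0.906 and Eif2s3y at 257 ± 4.94 and 269.5 ± 4.64. Their X-linked copies may take part of these reads.

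The remaining lists did not pass the list test in PGCLC_d3ag3. Of naive pluripotency genes 5 of 14 rose and 5 fell (adjusted p = 0.743), against 5 and 4 under quantile normalization. Of general pluripotency genes 2 of 11 rose and 6 fell (adjusted p = 0.523). Of formative and primed epiblast genes 2 of 18 rose and 11 fell (adjusted p = 0.0903). That list passed, down, with a pseudocount of 0.1 (adjusted p = 0.0387), no filter on low values (adjusted p = 0.0479) and median-of-ratios rescaling (adjusted p = 0.0458). Of neural ectoderm genes 1 of 5 rose and 2 fell (adjusted p = 0.748). Of endoderm genes 1 of 8 rose and 4 fell (adjusted p = 0.413). Of early germ cell genes 7 of 15 rose and 8 fell (adjusted p = 0.702). Of DNA methylation genes 1 of 9 rose and 4 fell (adjusted p = 0.717). Of DNA demethylation genes 2 of 8 rose and 2 fell (adjusted p = 0.702), against 3 and 2 after either rescaling. Of histone methylation genes 3 of 14 rose and 7 fell (adjusted p = 0.702). Of LIF and STAT3 targets 3 of 12 rose and 7 fell (adjusted p = 0.352). Of immediate early and dissociation stress genes 4 of 15 rose and 8 fell (adjusted p = 0.895). Of G2 and M genes 6 of 21 rose and 6 fell (adjusted p = 0.352), against 14 and 3 after median-of-ratios rescaling and 6 and 7 after quantile normalization. Of ribosomal protein genes 6 of 24 rose and 1 fell (adjusted p = 0.143), against 3 and 7 under quantile normalization, and the list passed, up, after median-of-ratios rescaling (adjusted p = 0.0176) and without PGCLC_d3ag3 replicate 2 (adjusted p = 0.0131). Of HOX genes 2 of 8 rose and 3 fell (adjusted p = 0.702), against 3 and 2 under quantile normalization. Of epithelial and mesenchymal genes 2 of 11 rose and 6 fell (adjusted p = 0.702). Adjusted over the list alone, the counts were as over all genes except for BMP targets (0 and 14), LIF and STAT3 targets (4 and 7) and ribosomal proteins (5 and 1). The list test pointed up where the median was down for naive pluripotency (-0.11), neural ectoderm (-0.21), early germ cell (-0.43), DNA demethylation (-0.05), immediate early (-0.39), HOX (-0.05), gonadal somatic (-0.02) and fibroblast genes (-0.31). The list means were -0.23, 0.48, 0.26, 0.05, -0.25, 0.01, -0.08 and -0.12 in that order.

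In limma 9560 of 13571 genes changed between PGCLC_d3ag3 and PGCLC_d3, 3483 higher and 6077 lower, or 889 and 2099 with a log2 change of at least 1. The median gene changed by -0.18, by -0.04 after median-of-ratios rescaling and by -0.002 after quantile normalization, and the share of changed genes that were higher was 36.4%, 47.5% and 49.9% in turn. No label gives a library batch, and none of the 12 list calls passed with an estimated correlation.

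**Figure D3:**
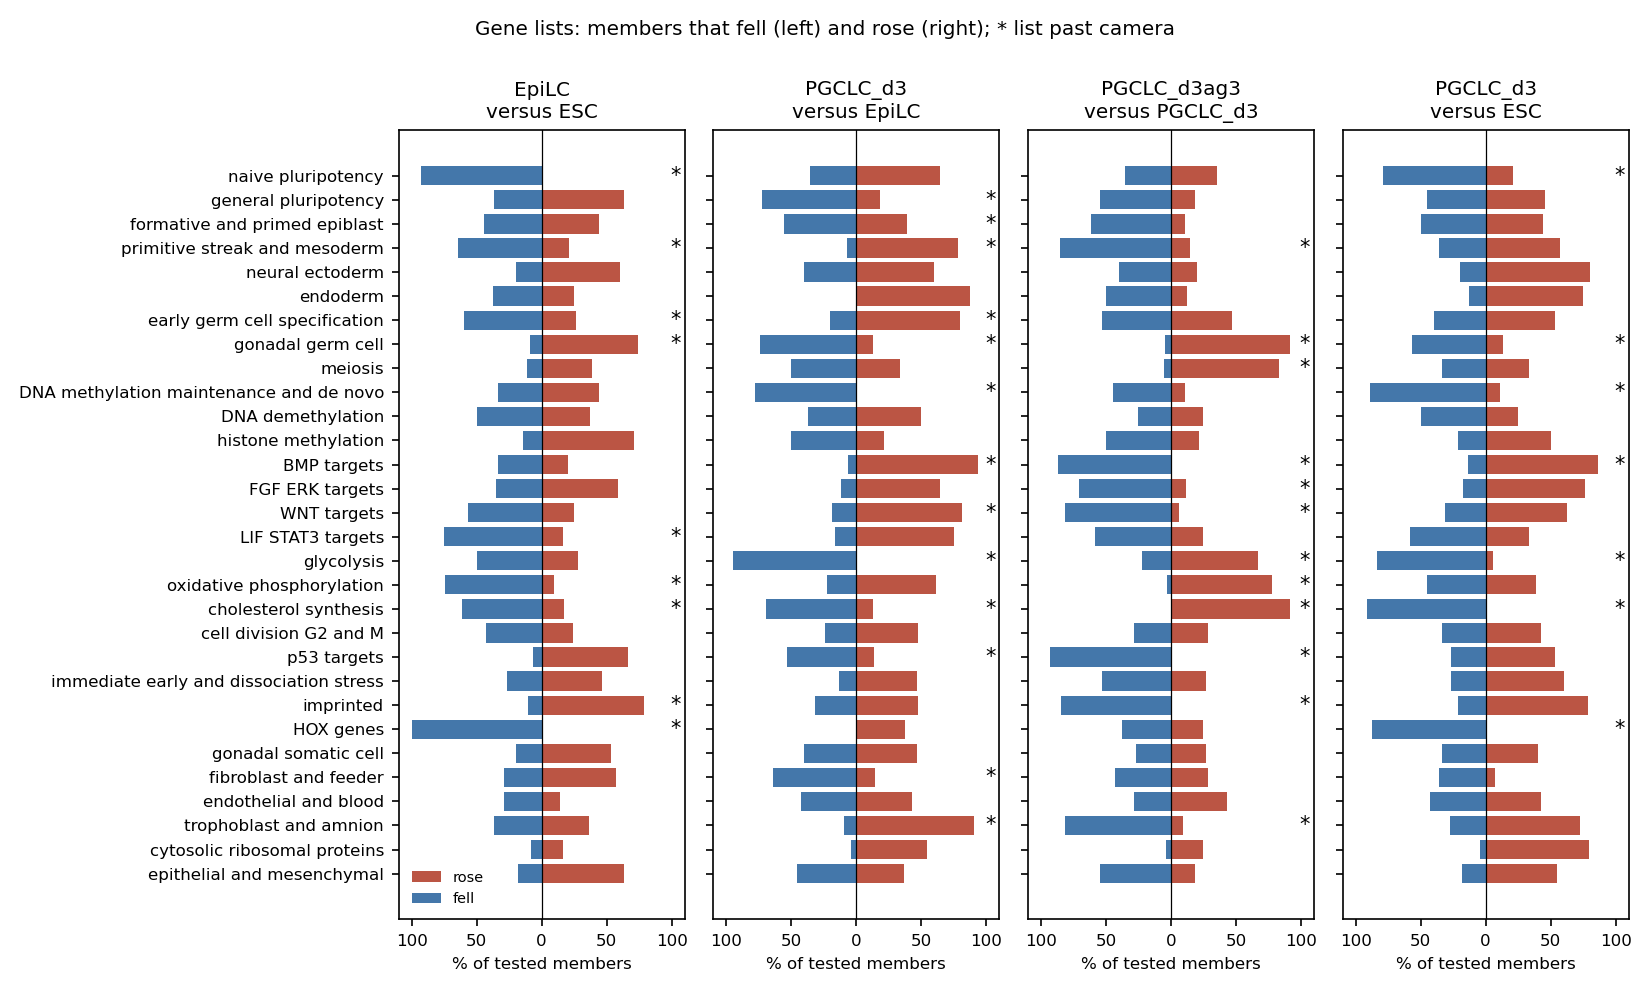
Share of tested members of each gene list that fell (bars to the left) and rose (bars to the right), in % of tested members on the x axis, for the 4 comparisons, with a star where the list passed camera with a correlation of 0.01. Gonadal germ cell genes fell from EpiLC to PGCLC_d3 (17 of 23) and rose in PGCLC_d3ag3 (21 of 23), and BMP targets did the opposite (14 of 15 rose, then 13 of 15 fell), while between EpiLC and PGCLC_d3 the rises and falls of oxidative phosphorylation (19/7), cell division (10/5) and ribosomal protein genes (13/1) became 10/12, 8/9 and 5/5 after median-of-ratios rescaling but 19/5, 9/6 and 20/1 under quantile normalization.

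Day 3 cells were also set against ESC, the start of the series. Both express pluripotency genes, at different levels. Nanog was at TPM 922 ± 14.9 in ESC and 159 ± 15.2 (SD, n = 2) in PGCLC_d3, a log2 change of -2.53 (SE 0.105), and Pou5f1 fell from 517 ± 1.27 to 186 ± 6.68. Sox2 was at 217 ± 8.55 and 222 ± 7.33 (log2 0.03, adjusted p = 0.746), with a sign that turned after median-of-ratios rescaling. Zfp42 fell from 599 ± 21.4 to 4.08 ± 0.576, Tfcp2l1 from 27.6 ± 6.05 to 0.208 ± 0.095, Klf4 from 47.2 ± 0.496 to 2.32 ± 0.024 and Esrrb from 118 ± 10.3 to 20.3 ± 0.292. Prdm1 rose from 0.053 ± 0.028 to 66.5 ± 1.55, Tfap2c from 36.0 ± 1.67 to 492 ± 7.50 and Prdm14 from 16.9 ± 0.867 to 86.0 ± 3.75.

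Kit rose by 2.98 on the log2 scale, Tbxt by 3.76 and Nanos3 by 3.12, whereas Dppa3 fell from 1309 ± 4.50 to 382 ± 9.58 and Dnmt3b from 149 ± 8.32 to 30.7 ± 4.40. The largest rises were in Psmb8 (0.040 ± 0.057 to 521 ± 12.5), Tspan8 (0.066 ± 0.093 to 390.4 ± 14.2), Ccnd2 (1.20 ± 0.495 to 333 ± 19.3), the ERK phosphatase gene Dusp9 (0.156 ± 0.172 to 154 ± 10.6) and Ap3b2 (0.012 ± 0.017 to 131 ± 2.53). The largest falls were in the autophagy receptor gene Calcoco2 (2136 ± 169 to 1.62 ± 1.32), Dnmt3l (1080.3 ± 57.7 to 0.490 ± 0.518), Pramel6 (643 ± 33.4 to 0.201 ± 0.203), the threonine dehydrogenase gene Tdh (683 ± 5.70 to 2.79 ± 0.204) and Dppa5 (196 ± 11.1 to 0.141 ± 0.110).

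Of 14 naive pluripotency genes 11 fell and 3 rose (adjusted p = 5.3e-04 and adjusted p = 0.538 with an estimated correlation). Fgf4 changed by log2 -6.93. DNA methylation genes fell in 8 of 9 and rose in 1 (adjusted p = 4.3e-04 and adjusted p = 0.538 with an estimated correlation). Zfp57, which protects imprints, fell from 78.8 ± 1.13 to 11.2 ± 0.393. HOX genes fell in 7 of 8 and rose in 0 (adjusted p = 7.1e-05 and adjusted p = 0.291 with an estimated correlation). Hoxa7 was at 0.438 ± 0.196 and Hoxa9 at 0.246 ± 0.012 in PGCLC_d3. Cholesterol synthesis genes fell in 21 of 23 and rose in 0 (adjusted p = 2.0e-08 and adjusted p = 0.491 with an estimated correlation). Log2 changes were -2.24 for Acat2 and -1.96 for Insig1. Glycolysis genes fell in 15 of 18 and rose in 1 (adjusted p = 1.0e-06 and adjusted p = 0.538 with an estimated correlation). Hk2 fell from 123 ± 11.8 to 12.1 ± 1.77, Hk1 from 122 ± 11.5 to 14.8 ± 1.27 and Pgk1 from 1946 ± 5.73 to 372 ± 2.37. Gonadal germ cell genes fell in 13 of 23 and rose in 3 (adjusted p = 0.00168 and adjusted p = 0.538 with an estimated correlation). Ddx4 was at 54.7 ± 4.17 in ESC and 1.29 ± 0.018 in PGCLC_d3, Fkbp6 at 8.35 ± 0.550 and 0.108 ± 0.032 and Gpat2 at 8.12 ± 1.03 and 0.391 ± 0.090. BMP targets rose in 13 of 15 and fell in 2 (adjusted p = 0.0101 and adjusted p = 0.538 with an estimated correlation). Among them were Id1 (2.88 ± 0.770 to 298 ± 27.9), Smad6 (0.791 ± 0.007 to 55.0 ± 4.69) and Bambi (15.1 ± 1.27 to 232 ± 20.8).

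The other lists did not pass the list test between PGCLC_d3 and ESC. Of general pluripotency genes 5 of 11 rose and 5 fell (adjusted p = 0.433), against 4 and 5 after median-of-ratios rescaling. Of formative genes 8 of 18 rose and 9 fell (adjusted p = 0.322). Of streak and mesoderm genes 8 of 14 rose and 5 fell (adjusted p = 0.933). Of neural ectoderm genes 4 of 5 rose and 1 fell (adjusted p = 0.322). Of endoderm genes 6 of 8 rose and 1 fell (adjusted p = 0.249). Of early germ cell genes 8 of 15 rose and 6 fell (adjusted p = 0.933). Of meiosis genes 6 of 18 rose and 6 fell (adjusted p = 0.227), against 5 and 7 after median-of-ratios rescaling and 3 and 10 under quantile normalization. Of DNA demethylation genes 2 of 8 rose and 4 fell (adjusted p = 0.449). Of histone methylation genes 7 of 14 rose and 3 fell (adjusted p = 0.933), against 4 and 5 after median-of-ratios rescaling. Of FGF and ERK targets 13 of 17 rose and 3 fell (adjusted p = 0.153). Of WNT targets 10 of 16 rose and 5 fell (adjusted p = 0.649). Of LIF and STAT3 targets 4 of 12 rose and 7 fell (adjusted p = 0.119). Of oxidative phosphorylation genes 12 of 31 rose and 14 fell (adjusted p = 0.227), against 14 and 10 under quantile normalization and 5 and 17 after median-of-ratios rescaling, where the list passed, down (adjusted p = 0.0376). Of G2 and M genes 9 of 21 rose and 7 fell (adjusted p = 0.496), against 6 and 12 after median-of-ratios rescaling. Of p53 targets 8 of 15 rose and 4 fell (adjusted p = 0.7), against 2 and 5 after that rescaling and 3 and 5 under quantile normalization. Of immediate early genes 9 of 15 rose and 4 fell (adjusted p = 0.598). Of imprinted genes 15 of 19 rose and 4 fell (adjusted p = 0.159). Of gonadal somatic cell genes 6 of 15 rose and 5 fell (adjusted p = 0.611), against 5 and 6 under quantile normalization. Of fibroblast genes 1 of 14 rose and 5 fell (adjusted p = 0.17). Of endothelial and blood genes 3 of 7 rose and 3 fell (adjusted p = 0.322). Of trophoblast and amnion genes 8 of 11 rose and 3 fell (adjusted p = 0.314). Of ribosomal protein genes 19 of 24 rose and 1 fell (adjusted p = 0.198), past the test, up, under quantile normalization (adjusted p = 0.00148), and of epithelial and mesenchymal genes 6 of 11 rose and 2 fell (adjusted p = 0.42). Adjusted over the list alone, the counts of rises and falls were as over all genes for the lists of this comparison. The list test pointed down where the median was up for general pluripotency (0.03), histone methylation (0.25), oxidative phosphorylation (0.1), cell division (0.02), p53 targets (0.25) and gonadal somatic genes (0.22), with list means of -0.33, 0.08, -0.07, 0.07, -0.09 and 0.25, and endothelial and blood genes had a median of 0 and a mean of -0.9.

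In limma 10448 of 13571 genes changed between PGCLC_d3 and ESC, 6733 higher and 3715 lower, or 3019 and 1663 with a log2 change of at least 1. The median gene changed by 0.25, by 0.05 after median-of-ratios rescaling and by 0.03 after quantile normalization, and the share of changed genes that were higher was 64.4%, 53.5% and 52.3% in turn. None of the 7 list calls passed with an estimated correlation.

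Genes such as Nanog, Sox2 and Dppa3 were lower in EpiLC than on either side of it. In all, 2552 genes were lower in EpiLC than in both ESC and PGCLC_d3, 59.0% of the genes that fell from ESC to EpiLC, and of these 642 were lower in PGCLC_d3 than in ESC, 1127 were higher and 783 did not pass the test between those groups. Conversely 2027 genes, among them Otx2, Pou3f1, Dnmt3b and Ddx4, were higher in EpiLC than in both, 42.2% of the genes that rose. Of these 576 were lower in PGCLC_d3 than in ESC, 730 were higher and 721 did not pass the test. Over all genes changed between PGCLC_d3 and ESC, 64.4% were higher. That share was 53.5% after median-of-ratios rescaling and 52.3% after quantile normalization. The splits therefore do not show that genes low in EpiLC rise past their ESC level in particular. With a log2 change of at least 1 in both comparisons, 531 genes were lower and 611 higher in EpiLC, so the balance depends on the threshold. Without that threshold, independent lists as long as those of the calls would share 2046 and 1327 genes. In 100 simulations all groups were unchanged and both comparisons used the same simulated EpiLC libraries. The calls then shared 0.02 genes on average and at most 1. Few genes are called in such data, so the simulations cannot show what shared libraries add when most genes are called. The 2 comparisons use the same 2 EpiLC libraries, which cannot be split further, so part of the excess may come from sharing them.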

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

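For 120 list results under the settings tried, 1565 values kept direction and side of the threshold, 26 came to pass, 49 no longer passed and 28 turned. Of the 49 lost calls, 41 were lost with an estimated correlation, under which 0 lists passed in each of the 4 comparisons. Camera then has only the 4 residual degrees of freedom. For HOX genes in EpiLC versus ESC the estimate was -0.092, below the preset 0.01, yet camera p went from 5.5e-06 to 0.00929. For meiosis genes in PGCLC_d3ag3 it was -0.007, and camera p went from 6.2e-09 to 0.00327. Other lists had higher estimates, such as 0.311 for gonadal germ cell genes. Correlation alone therefore does not account for all the lost calls. For 195 results for named genes, 2677 values kept both, 3 came to pass, 38 no longer passed and 8 turned. With an absolute log2 change of at least 1, the counts of changed genes were 3165 for EpiLC versus ESC, 4012 for PGCLC_d3 versus EpiLC, 2988 for PGCLC_d3ag3 versus PGCLC_d3 and 4682 for PGCLC_d3 versus ESC, and 531 genes were lower and 611 higher in EpiLC than on both sides, by construction of the threshold. Under every other setting these counts stayed within 1.5 times. With a library left out, where the lone sample is assumed to vary like the other groups, the counts ran from 7985 to 8305, 9055 to 9280, 8233 to 9288 and 9494 to 9931 in the order of the comparisons. The replicate number shared across groups was fitted as a replicate block, giving 9171, 10211, 9589 and 10478 changed genes and the same calls for all lists and named genes. Differences between replicates correlated at -0.037 to 0.066 between groups, so nothing shows that the numbers pair the samples.

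Results that turned passed neither in the main fit nor under the setting that turned them, and the cause was not tested. Some passed the other way under another setting. Ribosomal protein and oxidative phosphorylation lists in PGCLC_d3 versus EpiLC passed, up, under quantile normalization. In PGCLC_d3ag3 versus PGCLC_d3, ribosomal proteins passed, up, after median-of-ratios rescaling, and Uhrf1, up, under quantile normalization. Lists are given as -log10 p with the sign of the direction. With a pseudocount of 0.1, streak and mesoderm came to -0.006 and early germ cell to -0.007 in PGCLC_d3 versus ESC. Without a filter, endoderm came to 0.008 and endothelial and blood to 0.126 in EpiLC versus ESC, HOX to -0.118 in PGCLC_d3 versus EpiLC, immediate early to -0.017 and fibroblast to -0.187 in PGCLC_d3ag3 versus PGCLC_d3, and histone methylation to 0.052 in PGCLC_d3 versus ESC. Over genes with TPM of at least 5, HOX came to -0.047 and gonadal somatic to 0.026 in PGCLC_d3 versus EpiLC, and streak and mesoderm to -0.026 and WNT targets to -0.063 in PGCLC_d3 versus ESC. After median-of-ratios rescaling, oxidative phosphorylation came to -0.124, cell division to -0.103 and ribosomal proteins to -0.045 in PGCLC_d3 versus EpiLC, and immediate early to -0.050 and fibroblast to -0.139 in PGCLC_d3ag3 versus PGCLC_d3. Under quantile normalization, early germ cell came to -0.065, immediate early to -0.183, fibroblast to -0.105 and ribosomal proteins to -0.479 in PGCLC_d3ag3 versus PGCLC_d3, and oxidative phosphorylation to 0.102 and cell division to 0.055 in PGCLC_d3 versus ESC. For genes, the log2 change of Wnt3 in EpiLC was -0.047 under quantile normalization. In PGCLC_d3ag3 versus PGCLC_d3, Nanog was at 0.087 after median-of-ratios rescaling and Dnmt3b at 0.017 after it and 0.101 under quantile normalization, and Sox2 in PGCLC_d3 versus ESC was at -0.203 after median-of-ratios rescaling. With a library left out, ribosomal proteins in EpiLC ran from -0.411 to 0.763, streak and mesoderm in PGCLC_d3 versus ESC from -0.020 to 0.119, HOX in PGCLC_d3 versus EpiLC from -0.036 to 0.075 and fibroblast in PGCLC_d3ag3 from -0.005 to 0.145. Nanog in PGCLC_d3ag3 ran from -0.182 to 0.012, Uhrf1 there from -0.184 to 0.334, of which the highest passed the test, and Sox2 in PGCLC_d3 versus ESC from -0.005 to 0.075. Depth limits genes of a few reads, for which a value of 0 in 1 group need not mean absence, and the depth of PGCLC_d3ag3 is about 2 times that of PGCLC_d3. PGCLC_d3ag3 replicate 1 still had 6297 genes at 0, against 5099 in replicate 2. The PGCLC_d3 replicates had 5495 and 5574, so zeros did not follow depth alone.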

Other observations

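The genes of this part were chosen after their values were seen. Of 12 antigen presentation genes, 12 were higher in PGCLC_d3 than in EpiLC. The immunoproteasome gene Psmb9 was at TPM 1.61 ± 0.309 in EpiLC, 203 ± 8.29 (SD, n = 2) in PGCLC_d3 and 98.7 ± 4.06 in PGCLC_d3ag3, the peptide transporter gene Tap1 at 1.13 ± 0.200, 60.3 ± 4.56 and 7.70 ± 1.97, and B2m, which encodes the light chain of class I molecules, at 33.4 ± 6.31, 83.8 ± 4.03 and 15.8 ± 1.33. B2m was highest in ESC, at 207 ± 8.34, where Psmb9 was at 3.08 ± 0.293 and Tap1 at 0.945 ± 0.514. The regulators Nlrc5 and Irf1 were at 1.25 ± 0.140 and 369.8 ± 2.36 in PGCLC_d3, against 0.055 ± 0.027 and 7.26 ± 0.776 in EpiLC and 0.027 ± 0.007 and 41.8 ± 1.26 in ESC.

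Some genes were lower in PGCLC_d3 than in the other groups. The homeobox gene Rhox5 was at 427 ± 39.8 in ESC, 482 ± 4.74 in EpiLC, 31.7 ± 0.753 in PGCLC_d3 and 321 ± 5.05 (SD, n = 2) in PGCLC_d3ag3. Fcrla was at 329 ± 13.8, 173 ± 10.5, 1.96 ± 1.33 and 244 ± 0.962 in that order. Of the Y-linked genes, Rbmy1j, a germ cell RNA-binding protein gene, was low in all groups but PGCLC_d3ag3. It was at 1.32 ± 0.114 in ESC, 0.939 ± 0.068 in EpiLC, 0.349 ± 0.334 in PGCLC_d3 and 83.7 ± 0.581 in PGCLC_d3ag3.

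For the gonadal germ cell and meiosis genes higher in PGCLC_d3ag3 than in PGCLC_d3 (36 of 41 rose, median log2 change 3.26), the tests of donor cells and of scaling were chosen only after the result was seen. If female germ cells of the donor gonads, which the c-KIT depletion and the reporter sort were meant to remove, made up most of the sorted cells, Y-linked genes would be lower by log2 below -1, but Eif2s3y changed by 0.067 (SE 0.052). Kdm5d changed by -1.56, Uty by -1.42 and Ddx3y by 1.73, Usp9y rose from TPM 0.066 ± 0.028 to 3.89 ± 0.304 and Rbmy1j from 0.349 ± 0.334 to 83.7 ± 0.581, and of the X copies Kdm5c went from 26.7 ± 0.570 to 12.8 ± 1.03, Kdm6a from 27.5 ± 1.44 to 8.62 ± 0.339, Ddx3x changed by log2 -0.64 and Eif2s3 by 0.15 (adjusted p = 0.0687), which may share reads with Eif2s3y, so a smaller share of donor cells stays open. Greater depth, if it raised values, would raise other genes of the same level, but the highest median of 10000 random lists matched on the PGCLC_d3 level was 0.674. TPM is scaled within each library, so depth was not expected to raise levels and this test decides little. The median was 3.558 under quantile normalization, which brought the change of the median gene from -0.178 to -0.002. A shift of that size could not have ended a change of 3.26, so the outcome was set in advance. The values show only that this rescaling is small beside the change. A response of the cells to the gonadal environment is a hypothesis that these samples do not test. It cannot be told apart from 3 more days in culture or a change of medium.

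The HOX and CDX genes were higher in ESC than in EpiLC (10 of 10 tested, median ESC TPM 23.3, highest Cdx2 at 125), and both tests were chosen only after the result was seen. RNA of feeder fibroblasts could carry HOX transcripts, but Col1a1, the highest of 3 collagen genes, was at TPM 10.518 in ESC, below Cdx2, and the median of the fibroblast list in ESC was 0.395. Fn1, also on that list, was at 749.6 ± 169 in ESC and 205 ± 7.68 in EpiLC, and mouse reads may map poorly to the rat genome, so a small feeder share stays possible. WNT signalling raised by the GSK3 inhibitor of the ESC medium might explain the pattern, and the median log2 change of 14 other WNT targets was -0.289, with 7 lower in EpiLC and 4 higher, which leaves this open.

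For the antigen presentation genes higher in PGCLC_d3 than in EpiLC (12 of 12, median 4.99, and 12 of 12 lower again in PGCLC_d3ag3), the lists and the scaling test were chosen only after the result was seen, and the interferon prediction was written before its value was computed. If an interferon response was the cause, interferon-stimulated genes outside antigen presentation would be higher as a set, and the median of 22 tested genes was 2.196, with 17 higher and 5 lower, and in PGCLC_d3ag3 16 of the 22 fell and 3 rose (median -0.87), which goes with this explanation. Isg15 was at 2.65 ± 0.009 in EpiLC and 149.5 ± 2.21 in PGCLC_d3, Bst2 at 0.431 ± 0.244 and 93.6 ± 3.25 and Stat2 at 6.15 ± 0.203 and 88.0 ± 0.087, while Oasl, Rsad2, Ifi27, Cxcl10 and Cmpk2 were lower and Ifit1 was listed near 0. Under quantile normalization the median was 4.872, while the change of the median gene went from 0.211 to 0.013. Such a shift could not have ended a change of 4.99, so this scaling test decides little. It shows only that the rescaling is small beside the change.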
